A study of Mus musculus with 19 samples.

How the data were processed

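The values were the gene counts deposited by the authors, read pairs per gene that per the file headers came from featureCounts 1.6.3 in paired, reverse-stranded mode with the largest-overlap option on GRCm38 with Ensembl 96. The deposited notes also name cutadapt 1.16, FastQC, STAR, RSEM and SAMtools without giving their role or order. Each file had 55536 genes, all matched to GENCODE M21 by start, end and strand. The 16-week samples had 2 deposited files each, and these counts were summed. CPM are counts divided by the library total times the TMM factor.

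Differential expression was tested on counts with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr, a mean per group, all 19 libraries) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. A total of 15503 genes passed the filter. TMM factors were 0.455 to 1.476. Log2 CPM values, used in the gene list tests and the comparisons of sign between times, had a prior count of 2. The edgeR log2 fold changes kept the default of that package. Each fold change has the SE shown beside it where given, computed as the absolute log2 fold change over the square root of the F statistic. Gene lists, 22 of pathways and 11 of cell types, were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Counting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The lists, the model, the comparisons and the rule for naming genes were set before the data were examined.

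Genes named for each time were Mpc1, Mpc2 and the 10 largest rises and falls among genes past the threshold with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a predicted or clone name. Up to 4 members per list with the smallest adjusted p at each time were named too, those not past the threshold by value alone. CT010467.1 and Mpc1-ps are outside this rule and were chosen after their values were seen. Some genes that the rule selects are not reported here.

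Alternatives set before the data were examined were RLE and upper-quartile factors, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, a fit to the compared groups alone, thinning to the smallest library, mitochondrial genes left out, protein-coding genes alone, sex as a covariate, the earlier or the later 16-week file alone, and each library left out. After the data were seen these were added: the 18S share as a covariate, 16-week libraries over or under 20% 18S, rRNA genes left out, male libraries left out, and voom with quality weights.

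The pipeline was tested on simulated data in which 67, 67 and 66 genes had 1.5-, 2- and 4-fold changes. At 16 weeks the fit to all libraries recovered 32.8%, 70.1% and 95.5% of them with 76 false calls in 208, and the fit to the 16-week libraries alone 9%, 50.7% and 83.3% with 5 in 100. At 8 weeks the fit to all libraries recovered 35.8%, 77.6% and 100% with 1 false call in 143, and the 8-week libraries alone 77.6%, 95.5% and 100% with 9 in 191. In camera a simulated shifted list passed and an unshifted list did not. The genes of that simulation were independent. It therefore does not test lists of correlated genes, such as the extracellular matrix list (estimated correlation 0.73). The 2 files of a sample differed by a chi-square per gene of 1.34 to 3.15, against at least 6.305 between libraries of the same group. No sample was left out, and raw reads were not used here.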

Results

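Ventricular RNA was sequenced from wild-type mice (WT) and from mice in which Mpc1 had been deleted in the heart during adult life (KO), 8 or 16 weeks after the deletion was induced. Mpc1 encodes a subunit of the mitochondrial pyruvate carrier, which brings pyruvate from the cytosol into the mitochondrial matrix. The groups are called WT-8 (5 libraries), KO-8 (4), WT-16 (5) and KO-16 (5). The labels do not say whether each library came from a separate animal, so the p-values measure the spread between libraries. In the fit to all libraries both times shared an estimate of the spread for each gene. Its SEs and p-values therefore do not measure the spread of the compared libraries alone. The common coefficient of variation was 0.171 over all libraries, 0.24 at 16 weeks and 0.094 at 8 weeks. Library totals ranged from 17.4 to 27.5 M (mega) counted read pairs in WT-8, from 16.5 to 19.5 M in KO-8, from 8.63 to 19.7 M in WT-16 and from 9.54 to 26.9 M in KO-16. The gene CT010467.1, annotated on 18S ribosomal RNA and singled out after its values were seen, took 6.88% to 39.1% of the counts in WT-16 and 1.71% to 30.0% in KO-16. It took at most 0.07% in any 8-week library. Mitochondrial genes took 27.9% to 41.6% of the counts at 16 weeks and 20.6% to 27.25% at 8 weeks. Sex-linked transcripts marked replicate 5 of WT-16 and replicate 4 of KO-16 as male and the remaining libraries as female.

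**Figure D1:**
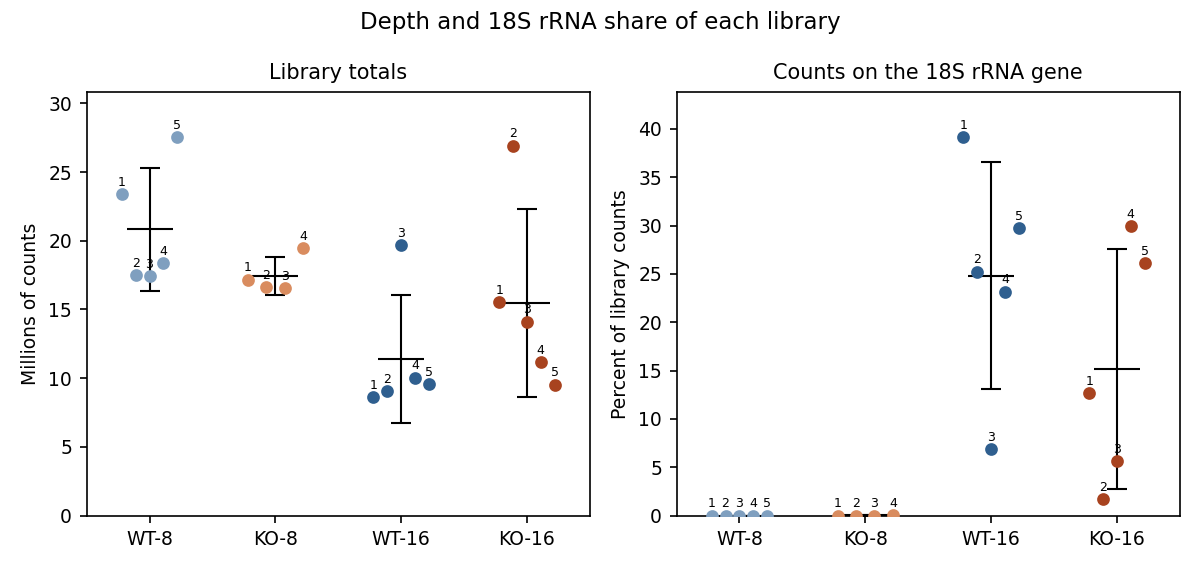
Library totals in M counts (left) and the percent of each library's counts on the 18S rRNA gene (right). Points are libraries numbered by replicate, and bars give the mean and SD of each group; the 18S share was 1.71% to 39.1% at 16 weeks and at most 0.07% at 8 weeks.

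Mpc1 fell at both times. The gene (ENSMUSG00000023861, GRCm38 chromosome 17, 8282904 to 8297661, plus strand) had 74.4 ± 6.82 CPM (SD, n = 5; counts scaled by library size) in WT-8 and 10.8 ± 1.62 (n = 4) in KO-8, a log2 fold change of -2.78 (SE 0.23, adjusted p = 8.28e-07). At 16 weeks it had 69.7 ± 9.30 CPM in WT and 15.1 ± 6.99 in KO (n = 5 each), a log2 fold change of -2.22 (SE 0.21, adjusted p = 6.77e-06). All KO libraries lay below all WT libraries of their time point. Replicate 1 of KO-16 kept the most Mpc1, 26.2 CPM, against 9.04 to 15.95 CPM in the other KO-16 libraries. Mpc2, the partner subunit of the carrier (chromosome 1, 165460637 to 165481214), had log2 fold changes of 0.05 (SE 0.13, adjusted p = 0.979) at 8 weeks and 0.15 (SE 0.13, adjusted p = 0.425) at 16 weeks. Its means were 79.5 and 82.4 CPM in WT-8 and KO-8, and 42.7 and 47.2 CPM in WT-16 and KO-16. The processed pseudogene Mpc1-ps on chromosome 12, named after its values were seen, fell with Mpc1, by 4.91 on the log2 scale at 8 weeks and by 4.03 at 16 weeks.

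**Figure D2:**
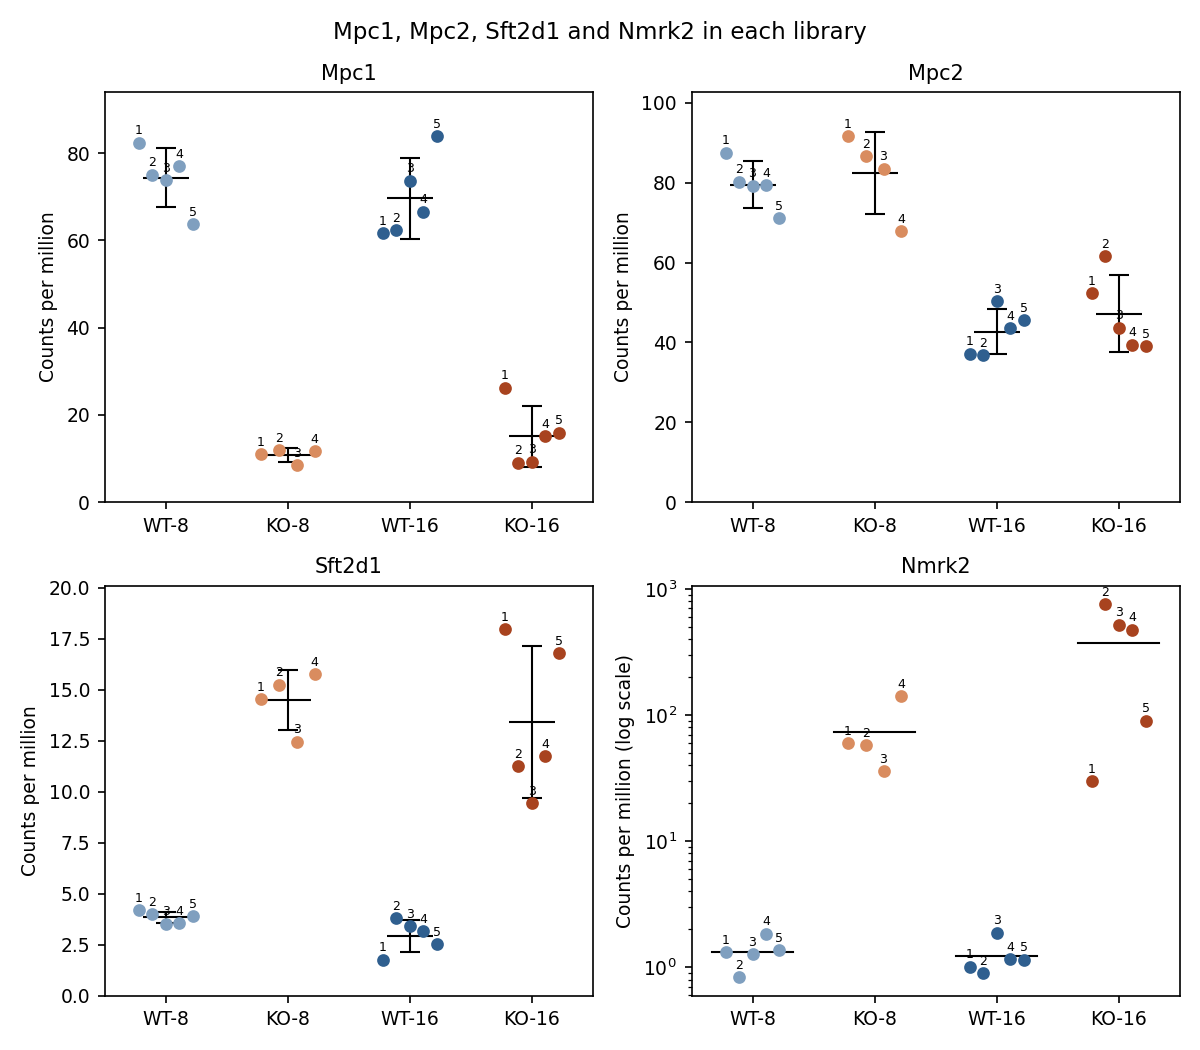
CPM of Mpc1, Mpc2, Sft2d1 and Nmrk2 (Nmrk2 on a log axis) in every library, numbered by replicate. Bars give the mean and SD (for Nmrk2 the mean only); Mpc1 was 8.42 to 26.2 CPM in KO and 61.7 to 83.9 CPM in WT.

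The 16-week comparison asked what the ventricle expressed late after the loss of Mpc1. In KO-16, 30 of 31 matrix, 10 of 14 hypertrophy and 12 of 18 glycolysis genes were higher, and 19 of 23 genes of fatty acid oxidation, 11 of 18 of branched-chain amino acid breakdown and 11 of 22 of calcium handling were lower. These counts were 23, 8, 3, 5, 6 and 1 in the 16-week libraries alone, and none of these lists passed with an estimated correlation (adjusted p from 0.28 to 0.411). With fry all of them passed in the fit to all libraries (adjusted p from 0.00017 to 0.014). In the 16-week libraries alone glycolysis (adjusted p = 0.0674) and calcium handling (adjusted p = 0.059) did not pass with fry. Of the further lists past camera, the cell cycle, interferon and both respiratory chain lists did not pass with fry (adjusted p from 0.058 to 0.225). Nmrk2, the muscle nicotinamide riboside kinase of NAD synthesis, rose from 1.22 ± 0.386 to 374 ± 307 CPM (SD, n = 5 each), a log2 fold change of 8.05 (SE 0.80, adjusted p = 6.77e-06). Acta1, skeletal alpha-actin, rose 40.1-fold (log2 SE 0.64). The matrix genes Thbs4 and Cilp rose 44.2-fold (log2 SE 0.82) and 39.2-fold (log2 SE 0.72). The rule for naming genes required groups without overlap, so that separation is no further support. For Thbs4 the lowest KO-16 library had 2.18 CPM and the highest WT-16 library 2.07. The log2 fold change of Thbs4, 5.47, was 4.61 without replicate 3 of KO-16 (177 CPM, against 2.18 to 62.7 in the other KO-16 libraries) and 4.44 with limma-voom, where it did not pass (adjusted p = 0.0757). That of Acta1, 5.32, was 5.94 without replicate 5 of WT-16. With limma-voom Nmrk2 was at 7.26 and Cilp at 4.57 (5.29 with edgeR), and both passed. Over all genes, 3181 of the 15503 tested passed an adjusted p of 0.05, 1735 higher and 1446 lower in KO, and 901 of them differed at least 2-fold. The balance of directions turned with the test: 1270 were higher and 1641 lower with limma-voom, and 1416 and 1606 with voom and quality weights. The 2 groups did not overlap in 665 genes, 4.29% of those tested against the 0.79% that chance gives, and 628 of these had passed. Fitted to the 16-week libraries alone, the same test called 356 genes, 237 higher and 119 lower, and all 356 were among the 3181. The spread was larger at 16 than at 8 weeks (coefficient of variation 0.24 against 0.094), and a simulated 16-week comparison in the fit to all libraries gave 76 false calls in 208, against 5 in 100 for the 16-week libraries alone. That simulation changed only 66 or 67 genes at each size, so its share of false calls does not carry over to the 3181.

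Large rises also included those of genes close to 0 in WT-16. A1cf, an RNA-editing cofactor, and Lman1l, a relative of an endoplasmic reticulum cargo receptor, had no count in any WT-16 library, and their KO-16 means of 4.32 and 2.23 CPM were at least 59.8-fold and 30.9-fold higher than a floor of 3 counts over the group. Esr1, estrogen receptor alpha, had 1.31 ± 0.897 CPM in WT-16 and 475 ± 339 in KO-16 (SD, n = 5 each; adjusted p = 0.00744), and did not pass with limma-voom and quality weights (adjusted p = 0.114). Ccn5, a matricellular protein, rose 22.9-fold, from a mean of 0.551 CPM in WT-16 to 11.8 in KO-16. The collagen genes Col22a1 and Col8a2 rose 18.8-fold (0.0886 to 2.98 CPM) and 16.6-fold (0.122 to 2.85 CPM). Their lowest KO-16 libraries lay barely above the highest WT-16 library, at 0.281 against 0.276 CPM and 0.351 against 0.333 CPM. Large falls included those of Acot1, an acyl-CoA thioesterase (7.17-fold), Cfap61, a cilium protein (6.93-fold), Rp1, a microtubule-associated protein (5.55-fold), and Cenpf, a centromere protein (5.38-fold). Mpc1, Lgals4, Ehhadh, Cngb3 and AU023070 fell too, with Ehhadh, the peroxisomal bifunctional enzyme of beta-oxidation, 3.69-fold lower. In the 16-week libraries alone Rp1 (adjusted p = 0.0909) and Cngb3 (adjusted p = 0.102) did not pass. Without replicate 3 of KO-16 the log2 fold change of Ccn5 was 3.70 (4.52 with it) and that of Col8a2 3.46 (4.05), and without replicate 3 of WT-16 Col22a1 was at 5.77 (4.23) and Col8a2 at 4.89. Without replicate 1 of KO-16 Acot1 was at -3.98 (-2.84 with it), Cfap61 at -3.70 (-2.79), Cenpf at -3.16 (-2.43), Lgals4 at -3.17 (-2.16) and Cngb3 at -2.87 (-1.87), and without replicate 5 Rp1 was at -3.12 (-2.47). Without replicate 2 of KO-16 Rp1 was at -1.97 and did not pass (adjusted p = 0.0531). With limma-voom Acot1 was at -3.45, Cfap61 at -3.38, Rp1 at -4.34, Lgals4 at -2.93 and Cngb3 at -2.84, and with voom and quality weights Cenpf was at -3.33 and AU023070 at -2.48 (-1.86 with edgeR).

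Extracellular matrix genes rose nearly as a whole at 16 weeks: 30 of 31 measured genes rose and none fell (31 and 0 adjusted over the list alone), with a median log2 fold change of 1.80. Postn, the matricellular periostin, went from 38.5 to 275 CPM (log2 fold change 2.82, SE 0.39, adjusted p = 0.000225). Replicate 1 of KO-16 had 46.7 CPM of Postn, below the 50.0 CPM of replicate 3 of WT-16. Col8a1 rose 9.15-fold, Col3a1 3.49-fold and Col6a1 2.10-fold. The list stood apart from other genes (adjusted p = 2e-18), and with an estimated correlation the adjusted p = 0.28. In the 16-week libraries alone 23 of 30 rose. Of the 10 fibroblast markers 4 rose (4 adjusted over the list alone), among them Pi16 (2.91-fold) and Mfap5 (4.08-fold), while Pdgfra had a log2 fold change of 0.08 (SE 0.12, adjusted p = 0.689). The fibroblast list did not pass in camera (adjusted p = 0.0795, and adjusted p = 0.419 with an estimated correlation) but passed with fry (adjusted p = 0.0151). Over 20% 18S it passed in camera (adjusted p = 0.0229). In the 16-week libraries alone it passed with neither camera nor fry (adjusted p = 0.0575 and 0.0659).

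Of 14 hypertrophy and fetal program genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). Nppa, atrial natriuretic peptide, went from 111 ± 126 to 1203 ± 948 CPM (SD, n = 5 each), a log2 fold change of 3.41 (SE 0.66, adjusted p = 0.00232; 4.40 without replicate 3 of WT-16). Ankrd1, a stress-responsive sarcomere protein, rose 5.97-fold (log2 SE 0.34), and Fhl1, a LIM-domain protein of the sarcomere, 5.23-fold. The list's median log2 fold change was 2.13 (adjusted p = 3.68e-06, and adjusted p = 0.28 with an estimated correlation), and 8 members rose in the 16-week libraries alone. Replicates 1 and 5 of KO-16 lay lowest among the KO-16 libraries for Nmrk2, Acta1 and Nppa. They had 29.9 and 90.4 CPM of Nmrk2 (others 474 to 757) and 127 and 262 of Acta1 (others 862 to 1776). For Nppa they had 264 and 207 CPM (others 1375 to 2352), both below replicate 3 of WT-16 (329 CPM).

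Fatty acid genes moved the other way. Of 23 genes of fatty acid uptake and oxidation 19 fell and none rose (20 and 0 adjusted over the list alone), with a median log2 fold change of -0.64. Lpl, lipoprotein lipase, went from 3685 ± 371 to 1638 ± 642 CPM (SD, n = 5 each; log2 fold change -1.17, SE 0.18, adjusted p = 0.000563). Cpt2, a carnitine palmitoyltransferase of the inner membrane, fell by 0.69, Acsl1, an acyl-CoA synthetase, by 0.65 and Etfa, of electron transfer flavoprotein, by 0.62 on the log2 scale. Of 16 PPAR-alpha target genes 13 fell and none rose (15 and 0 adjusted over the list alone; median -0.73), among them Acot1, Ehhadh and Acot2, a mitochondrial thioesterase (2.33-fold). The adjusted p-values were 1.37e-12 for the oxidation list and 4.56e-09 for the PPAR-alpha list, and both were 0.28 with an estimated correlation. In the 16-week libraries alone 5 members of each list fell.

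Glucose uptake and glycolysis had 12 of 18 genes higher and 1 lower (14 and 1 adjusted over the list alone). Gapdh rose 2.02-fold (log2 SE 0.17, adjusted p = 0.00104), Pfkp, a phosphofructokinase, 2.89-fold and Hk2, hexokinase 2, 1.73-fold. The median was 0.61 (adjusted p = 0.000613, and adjusted p = 0.411 with an estimated correlation), and 3 genes rose in the 16-week libraries alone. The glycolysis list did not pass over 20% 18S (adjusted p = 0.0599; 4 genes rose), and 6 genes rose with the 18S share as a covariate and 5 without the male libraries. Of 25 genes of pyruvate entry and use, 6 rose and 11 fell (7 and 12 adjusted over the list alone; adjusted p = 0.0496, and adjusted p = 0.411 with an estimated correlation). The genes that rose included Pdhb, a pyruvate dehydrogenase subunit (1.46-fold, log2 SE 0.11). Those that fell included Mpc1, Slc16a7, a monocarboxylate transporter (2.54-fold), Pdp2, a phosphatase that activates pyruvate dehydrogenase (1.98-fold), and Gpt2, which makes alanine from pyruvate (1.79-fold). Mpc1 and 1 other member fell in the 16-week libraries alone. Without replicates 1, 3 or 5 of WT-16 or 3 or 5 of KO-16 the pyruvate list did not pass (adjusted p = 0.0606, 0.0831, 0.0734, 0.0768 and 0.188), nor without the male libraries (adjusted p = 0.0589).

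Breakdown of branched-chain amino acids had 11 of 18 genes lower and none higher (13 and 0 adjusted over the list alone; median -0.46). Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase, was 2.53-fold lower (log2 SE 0.25, adjusted p = 0.00198), Bckdhb, a subunit of that enzyme, 1.75-fold lower, and Mccc1, of leucine breakdown, 1.74-fold lower. The adjusted p = 9.27e-07, and adjusted p = 0.28 with an estimated correlation. In the tricarboxylic acid cycle 7 of 18 genes fell (9 adjusted over the list alone), Idh2 by 0.67 and Sdha by 0.53 on the log2 scale, with adjusted p = 0.000221 and adjusted p = 0.411 with an estimated correlation. Of 22 genes of calcium handling and ion channels 11 fell and 1 rose (13 and 1 adjusted over the list alone). Atp2a2, the calcium pump SERCA2, was 1.84-fold lower (log2 SE 0.17, adjusted p = 0.00218), Pln, its inhibitor phospholamban, 1.66-fold and Kcnv2, a potassium channel subunit, 4.95-fold lower (log2 fold change -2.31, and -3.75 without replicate 1 of KO-16). That list had adjusted p = 5.2e-05, and adjusted p = 0.396 with an estimated correlation. In the 16-week libraries alone 6 branched-chain genes, 1 calcium gene (Atp2a2) and no tricarboxylic acid cycle gene passed.

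Of 13 mitochondrially encoded respiratory chain genes 6 fell (7 adjusted over the list alone), among them mt-Nd5 by 1.21 and mt-Nd2 by 0.94 on the log2 scale, with a median of -0.68 and adjusted p = 0.00221 (adjusted p = 0.419 with an estimated correlation). The median was -0.67 in the libraries over 20% 18S (4 WT and 2 KO; adjusted p = 0.000429, 3 genes fell) and -0.46 with the 18S share as a covariate (adjusted p = 0.00919, 1 fell). Without the male libraries no member fell past the test (median -0.48, adjusted p = 0.0350). Under 20% 18S, where the WT side is replicate 3 alone and decides nothing on the list, it was 0.16 (adjusted p = 0.978), and mt-Nd1, -0.70 in the full comparison, was 0.07. Nuclear-encoded respiratory chain genes had 6 of 29 lower, such as Ndufs1 (1.41-fold; 6 adjusted over the list alone), and a median of -0.12 (adjusted p = 0.033, and adjusted p = 0.587 with an estimated correlation). No member of either list passed in the 16-week libraries alone, and the nuclear list did not pass without replicates 3 or 5 of WT-16 or 3 or 5 of KO-16 (adjusted p = 0.138, 0.0529, 0.0896 and 0.468), nor without the male libraries (adjusted p = 0.0579). Of 22 ATF4 stress response genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), with Pycr1, of proline synthesis, 4.12-fold and Atf4 1.54-fold higher and Aldh1l2, of mitochondrial folate metabolism, 2.62-fold lower; the adjusted p was 0.0221, and adjusted p = 0.419 with an estimated correlation. None of 15 measured ATF4 genes rose and 1 fell in the 16-week libraries alone. The ATF4 list did not pass in the libraries over 20% 18S (adjusted p = 0.602; 1 gene rose and 1 fell), with the 18S share as a covariate (adjusted p = 0.0639), or without replicate 1 or 2 of KO-16 (adjusted p = 0.0583 and 0.0630). Of 15 cell cycle genes 8 rose (11 adjusted over the list alone; median 1.94), led by Bub1 (11.3-fold) and Top2a (3.83-fold), neither of which passed without replicate 2 of KO-16 (adjusted p = 0.0509 and 0.154), nor Top2a with limma-voom (adjusted p = 0.104). Without that replicate the cell cycle median was 0.98, and with limma-voom 1.25. Over 20% 18S none of the cell cycle genes rose and the list did not pass (adjusted p = 0.118); 1 rose with the 18S covariate and 1 without the male libraries. The cell cycle list had adjusted p = 0.00379, and adjusted p = 0.419 with an estimated correlation, with 4 members measured and none past the test in the 16-week libraries alone.

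Some markers of blood and vessels passed at 16 weeks, and fewer did in the 16-week libraries alone, where none of 5 erythroid, 1 of 10 endothelial, 1 of 9 smooth muscle and none of 9 macrophage markers rose. Of 7 erythroid genes 5 rose (7 adjusted over the list alone; median 1.88), among them Hbb-bs, a beta-globin (log2 fold change 2.70, SE 0.61). Replicate 3 of KO-16 had 838 CPM of Hbb-bs and the other KO-16 libraries 24.3 to 344, against 25.3 to 79.6 CPM in WT-16, and without that replicate the log2 fold change was 1.73 (the list's median 1.23). With limma-voom Hbb-bs did not pass (adjusted p = 0.0660). Without the male libraries 1 erythroid gene rose and the list did not pass (adjusted p = 0.0589). Of 10 endothelial markers 6 rose (8 adjusted over the list alone), such as Emcn (1.66-fold) and Pecam1 (1.27-fold). The adjusted p-values were 0.00794 and 0.00255, and 0.419 and 0.38 with an estimated correlation. Of 9 smooth muscle and pericyte markers 3 rose, Tagln 2.67-fold among them, and Abcc9 fell by 0.99 (4 and 1 adjusted over the list alone). Of 10 macrophage markers C1qc (2.10-fold) and Cd68 (1.83-fold) rose and Mrc1 fell by 0.25 (5 and 1 adjusted over the list alone). Of 4 Schwann cell markers 1 fell (2 adjusted over the list alone), and of 5 mesothelial markers Wt1 fell, by 0.67 (1 adjusted over the list alone). None of the 4 atrial, 2 lymphocyte and 2 neutrophil markers measured passed, and Plin4, the adipocyte marker measured, had a log2 fold change of -0.34 (SE 0.14, adjusted p = 0.0948). Single libraries differed in atrial markers: Myl7 had 87.8 CPM in replicate 3 of WT-16 and 0 to 15.65 in the other WT-16 libraries, and 0.558 to 48.1 in KO-16. The atrial list rose over 20% 18S (4 WT and 2 KO; 4 markers rose, median 3.07, adjusted p = 0.00512). Under 20% 18S, where replicate 3 of WT-16 is the only WT library, the median was -2.80 for the atrial list and -7.31 for the adipocyte list. These 2 values rest on the content of that library.

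In each of the other pathway lists at most 7 genes passed at 16 weeks. Adult sarcomere genes had 4 of 19 higher, such as Des (1.39-fold), and 3 lower (6 and 4 adjusted over the list alone). Antioxidant genes had 4 of 18 higher, such as Nqo1 (2.01-fold), and 2 lower, such as Sod1 (4 and 2 adjusted over the list alone). Interferon response genes had 3 of 15 higher, with Rsad2 1.88-fold (3 adjusted over the list alone; adjusted p = 0.0123 for the list, and adjusted p = 0.419 with an estimated correlation). Inflammatory genes had Serpina3n higher (4.19-fold; log2 fold change 2.07, and 2.83 without replicate 5 of WT-16) and Cxcl12 lower (1.63-fold) of 12 (4 and 2 adjusted over the list alone). Circadian clock genes had 3 of 15 lower, Per1, Hlf and Nr1d2 (3 adjusted over the list alone; adjusted p = 0.0402 for the list, and adjusted p = 0.411 with an estimated correlation). Ketone body genes had Bdh1, beta-hydroxybutyrate dehydrogenase, higher (2.74-fold) and 2 lower, such as Acat1, of 5 (1 and 2 adjusted over the list alone). Glutamate and aspartate anaplerosis had Gpt2 and Slc25a22 lower of 12, mitochondrial biogenesis regulators had Perm1 higher and Gabpa and Ppargc1a (1.87-fold) lower of 14, and mitochondrial chaperones had Hspd1, Hspa9 and Clpx lower of 9. Adjusted over the list alone, these had 0 and 2, 1 and 4, and 0 and 4 genes higher and lower. Rsad2 of the interferon genes and Bdh1 rose in the 16-week libraries alone, and no other member of the lists in this paragraph passed. The interferon list did not pass without replicate 5 of WT-16 (adjusted p = 0.100), nor the clock list without replicates 1 or 5 of WT-16 or 2 or 5 of KO-16 (adjusted p = 0.0863, 0.103, 0.0685 and 0.0893). Neither list passed over 20% 18S (adjusted p = 0.149 for interferon and 0.0935 for the clock), with the 18S covariate (adjusted p = 0.0514 and 0.0914) or without the male libraries (adjusted p = 0.0809 and 0.0629).

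The count of 16-week genes rested on single libraries: it was 1462 without replicate 2 of KO-16, 1976 without replicate 3 and 4888 without replicate 5. It was 1632 in the libraries over 20% of counts on the 18S gene (4 WT and 2 KO), 81 in those under 20% (1 WT and 3 KO), 1649 with the 18S share as a covariate and 1706 without the male libraries. Mrc1, Perm1, Slc25a22, Ppargc1a, Serpina3n and mt-Nd2 each lost the call with any of at least 6 of the 10 libraries left out.

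**Figure D3:**
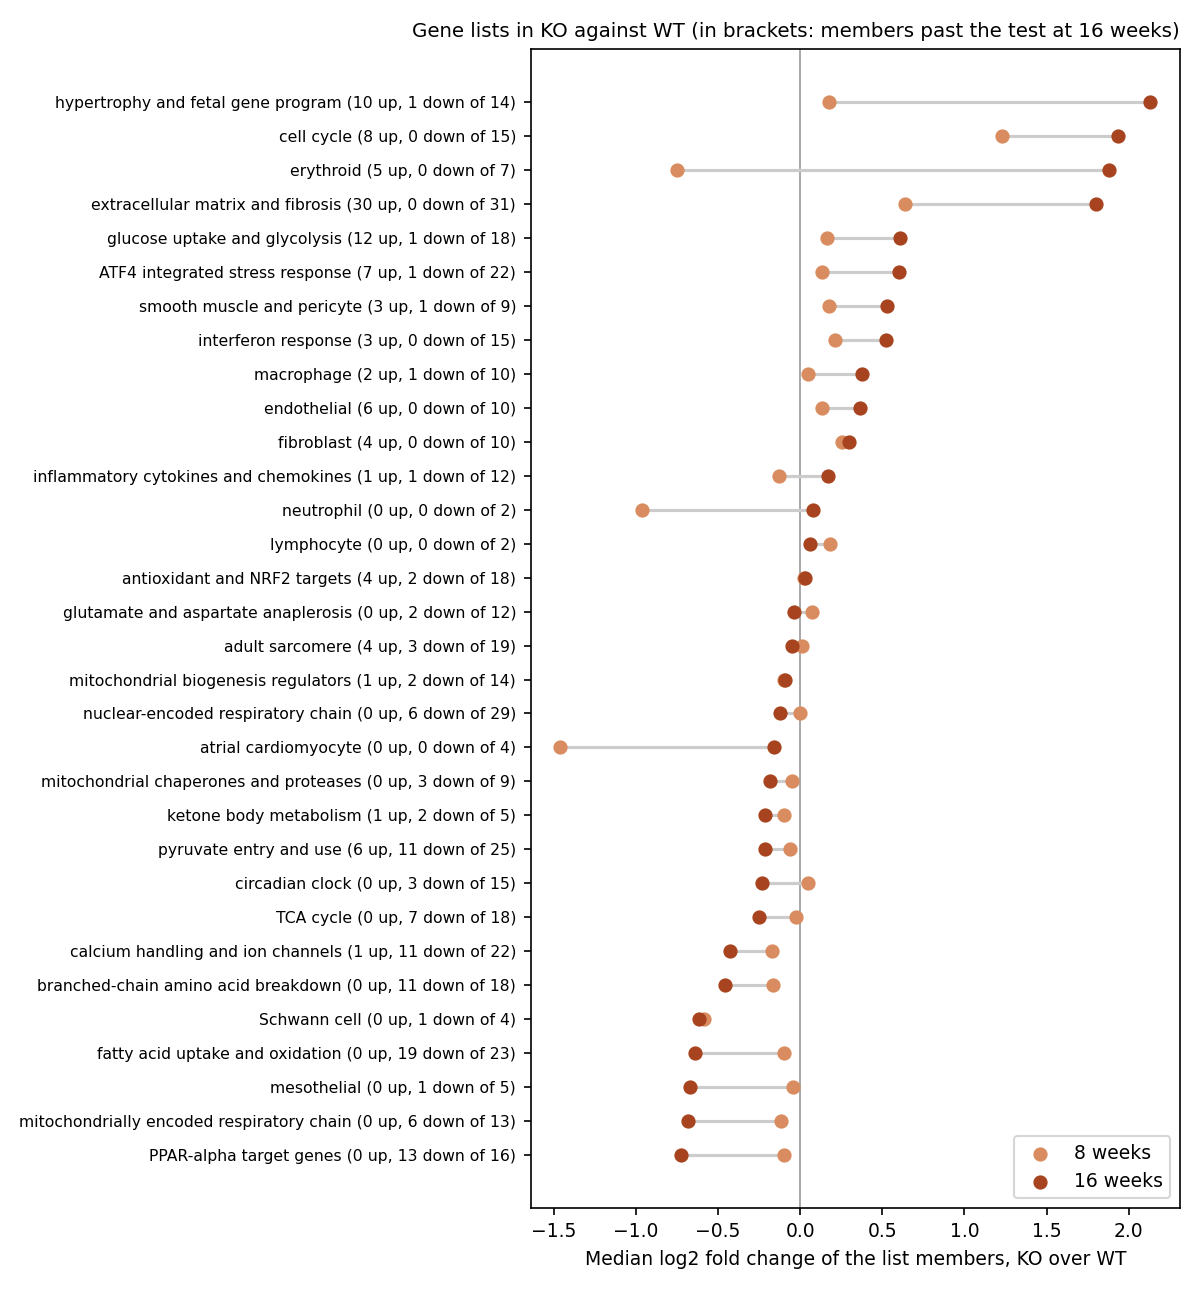
Median log2 fold change of KO over WT for each gene list with at least 2 measured members, at 8 weeks (light) and 16 weeks (dark). Brackets count the members higher and lower past the test at 16 weeks; the medians at 16 weeks run from -0.73 for PPAR-alpha targets to 2.13 for the hypertrophy program.

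The 8-week comparison asked which changes were there at the earlier time. Nmrk2 rose from 1.33 ± 0.358 to 73.6 ± 46.1 CPM (SD, n = 5 and 4; log2 fold change 5.78, SE 0.69, adjusted p = 0.000142), and Acta1 from 64.7 to 497 CPM (log2 fold change 2.94, SE 0.58, adjusted p = 0.0295). Grin2c, a subunit of the NMDA receptor, rose by 2.60 (SE 0.38), and Sft2d1, a vesicle transport protein whose gene starts downstream of Mpc1 on the same strand (chromosome 17, 8311102 to 8327442), from 3.84 ± 0.284 to 14.5 ± 1.45 CPM (log2 fold change 1.92, SE 0.16, adjusted p = 8.28e-07). Ptgds, prostaglandin D2 synthase, rose by 1.46 (SE 0.22), Fmn1 by 1.13, Lgi2 by 1.09, Msrb1 by 1.06, Nabp1 by 0.97 and Hspb6, a small heat shock protein, by 0.87. Besides Mpc1, Irs2, an insulin receptor substrate, fell by 1.35 (SE 0.27), Otud1 by 1.15, Pirt by 0.98, Ano10 by 0.94, Bcl2l11, the pro-apoptotic protein BIM, by 0.86, Slc7a1, a cationic amino acid transporter, by 0.80, Tcp11l2 by 0.60 and Qsox2 by 0.53. In total 31 genes passed, 17 higher and 14 lower in KO, 18 of them by at least 2-fold. The calls of Acta1 (adjusted p = 0.0550 to 0.153) and Hspb6 (adjusted p = 0.0688 to 0.153) were lost whichever 8-week library was left out, and those of Lgi2, Nabp1, Irs2, Otud1, Pirt, Ano10, Bcl2l11, Slc7a1, Tcp11l2 and Qsox2 without any of at least 4 of them.

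With the 8-week libraries alone, whose spread was smaller, 1245 of 15173 genes passed, 652 higher and 593 lower, and 30 of the 31 were among them. Among the 15503 genes tested in the fit to all libraries, the groups did not overlap in 1665, 10.74% against the 1.59% that chance gives. In the 8-week libraries alone extracellular matrix genes had 22 of 31 higher and none lower (25 and 1 adjusted over the list alone), among them Cilp (log2 fold change 2.28) and Col3a1 (0.79). Cell cycle genes had 10 of 15 higher (13 adjusted over the list alone), such as Top2a (1.32) and Ccna2 (1.33). Hypertrophy genes had 6 of 14 higher and 1 lower (6 and 1 adjusted over the list alone), with Nppa at 2.22, Fhl1 at 1.48 and Ankrd1 at 1.09. Calcium genes had 8 of 22 lower and 1 higher, with Atp2a2 at -0.38 (10 and 1 adjusted over the list alone), branched-chain genes had 5 of 18 lower, with Ppm1k at -0.57 (7 adjusted over the list alone), and glycolysis genes had 4 of 18 higher, with Gapdh at 0.58, and 1 lower (8 and 2 adjusted over the list alone). Of the fatty acid genes Lpl (-0.60), Echs1 and Etfb fell, and of the PPAR-alpha targets 2 fell, Ehhadh among them, and Plin2 rose. The PPAR-alpha list did not pass in camera (adjusted p = 0.439). The interferon list passed (adjusted p = 0.00999), with 1 of 15 measured genes higher, but not with an estimated correlation (adjusted p = 0.742). For the other lists of this paragraph the adjusted p-values in that fit were 1.22e-16 for the matrix list, 6.86e-09 for cell cycle, 0.000367 for hypertrophy and for calcium handling, 7.16e-05 for branched-chain breakdown, 0.00999 for glycolysis and 0.00367 for fatty acid oxidation. With an estimated correlation they were 0.281, 0.371, 0.358, 0.534, 0.568, 0.586 and 0.742. With fry they were 0.00784, 0.0252, 0.00794, 0.0404, 0.0388, 0.0532 and 0.185.

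With the spread of all libraries 2 hypertrophy genes (5 adjusted over the list alone) and Mpc1 of the pyruvate list passed at 8 weeks, and no member of the other lists did. Adjusted over the list alone, 10 cell cycle genes, 2 matrix genes and 3 glycolysis genes rose there. Among markers, fibroblast (median 0.26, adjusted p = 0.00883), smooth muscle (0.17, adjusted p = 0.0418) and endothelial lists (0.14, adjusted p = 0.0242) lay higher and Schwann cell markers lower (-0.58, adjusted p = 0.0476). With an estimated correlation their adjusted p-values were 0.411, 0.384, 0.585 and 0.52. With fry no list passed at 8 weeks in the fit to all libraries (lowest adjusted p = 0.485). Left-out libraries ended the calls of the fibroblast (replicate 3 of KO-8, adjusted p = 0.161), endothelial (3 and 4 of KO-8, 1 of WT-8; adjusted p = 0.0723, 0.0999 and 0.0521) and smooth muscle lists (2 and 4 of KO-8, 1 and 5 of WT-8; adjusted p = 0.0880, 0.132, 0.0722 and 0.0554). The Schwann cell call was lost without replicates 3 or 4 of KO-8 or 1, 3, 4 or 5 of WT-8 (adjusted p = 0.0509 to 0.128). The erythroid genes ran the other way from 16 weeks, with a median of -0.75 (adjusted p = 0.0134, and adjusted p = 0.628 with an estimated correlation; adjusted p = 0.0817 without replicate 1 of KO-8). The count of 31 rested on single libraries: it was 17 and 20 without replicates 2 and 3 of WT-8, and 16, 15, 15 and 18 without replicates 1, 2, 3 and 4 of KO-8. Replicate 1 of WT-8 had 1314 CPM of Esr1 and 2.25 CPM of A1cf, against 0.629 to 1.163 and 0 CPM in the other WT-8 libraries, and without it 29 genes passed.

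**Figure D4:**
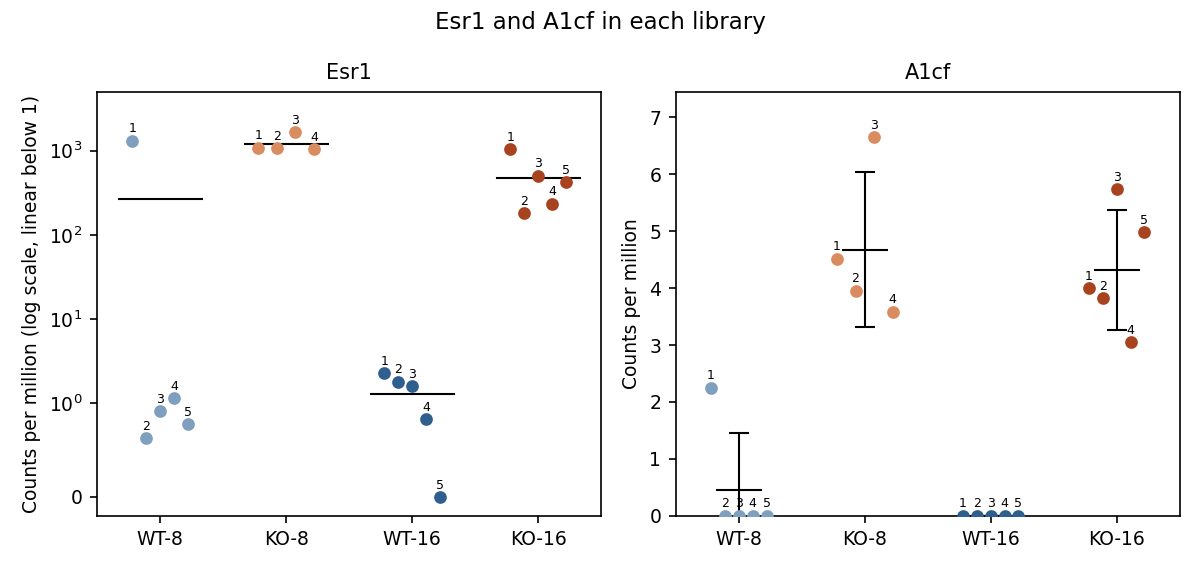
CPM of Esr1 (log axis, linear below 1) and A1cf in every library, numbered by replicate. Bars give group means and, for A1cf, the SD; replicate 1 of WT-8 is the WT library with both signals, at 1314 and 2.25 CPM.

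The knockout effect at 16 weeks was then set against that at 8 weeks. Of the 17 genes higher at 8 weeks 15 were higher at 16 weeks, where 1.9 were expected from independent calls (Fisher's exact test, two-sided p = 5.6e-13), and of the 14 lower 10 were lower (1.31 expected, Fisher's exact p = 3.41e-08). None went in opposite directions. The Fisher p-values treat genes as independent, and both sets of calls shared an estimate of the spread, so these p-values do not measure replication between libraries. Across genes, which are not independent replicates, the fold changes at the 2 times had a Pearson r of 0.568 and a Spearman rho of 0.463. With each time fitted alone 139 genes were higher and 68 lower at both, against 10.42 and 5.21 expected, and none was opposite. Nmrk2 had a log2 fold change of 8.05 at 16 and 5.78 at 8 weeks and Acta1 5.32 and 2.94, but the test of the difference gave no gene past the threshold (edgeR, 2000 genes at an unadjusted p under 0.05; 30 genes with DESeq2, 0 with limma-voom, and 527 with limma-voom and library quality weights). Without replicate 1 of KO-16 the edgeR count was 613, and without replicate 5 it was 114. The 25 genes past the test at both times became 14 and 16 without replicates 2 and 5 of WT-8, and 15, 15, 13 and 15 without replicates 1, 2, 3 and 4 of KO-8. The difference was 2.27 for Nmrk2 (adjusted p = 0.386), 2.38 for Acta1 (adjusted p = 0.312), 0.56 for Mpc1 (adjusted p = 0.421) and 0.09 for Mpc2 (adjusted p = 0.842).

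As sets, 14 lists differed in effect between the times. The matrix list had a median difference of 1.25 (16 minus 8 weeks, log2), the hypertrophy list 1.06, glycolysis 0.43, fatty acid oxidation -0.56, PPAR-alpha targets -0.67 and erythroid genes 2.60. Their adjusted p-values were 4.68e-13, 0.000842, 0.0275, 1.26e-12, 4.27e-11 and 1.55e-05. With an estimated correlation these calls were lost, with adjusted p = 0.589 for glycolysis, 0.347 for PPAR-alpha targets and 0.352 for the other 4. Adjusted over the list alone 27 matrix genes had a larger effect and 14 oxidation genes a lower one at 16 weeks. The other 8 lists were branched-chain breakdown, the tricarboxylic acid cycle, calcium handling, the circadian clock, both respiratory chain lists, endothelial markers and ATF4 targets, and these calls too were lost with an estimated correlation (adjusted p = 0.352 to 0.613). With fry none of the 14 lists passed (adjusted p = 0.0744 to 0.571).

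**Figure D5:**
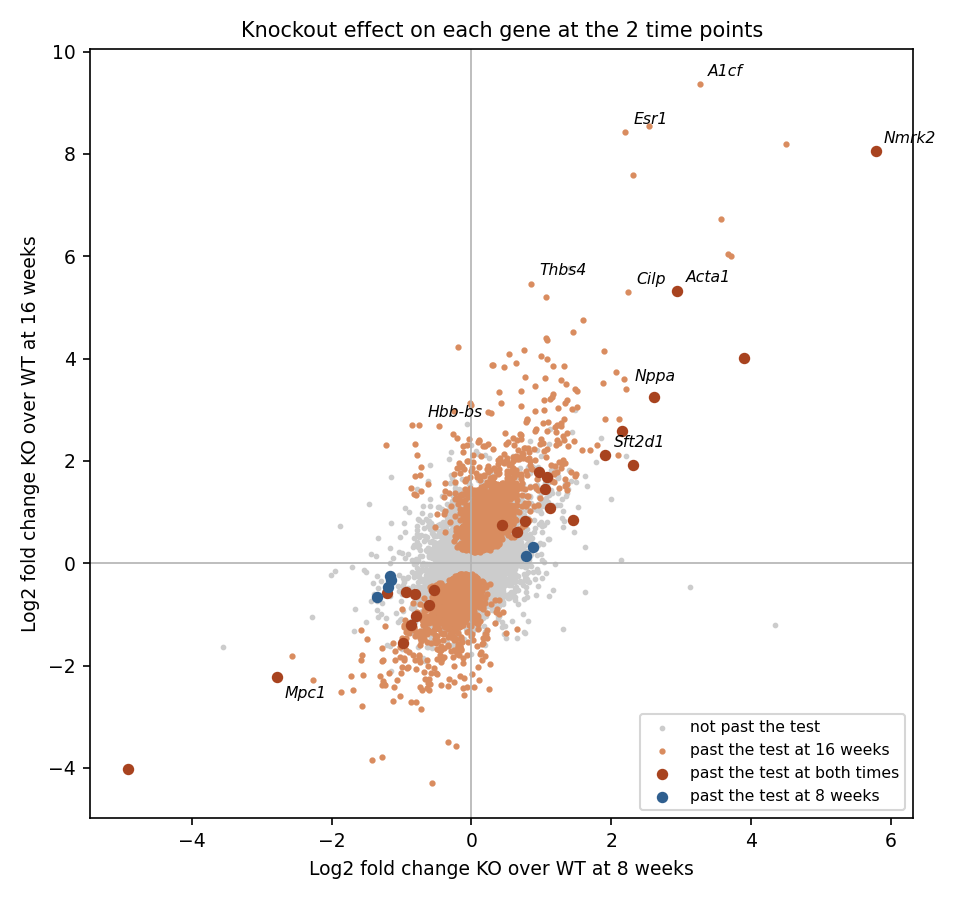
Log2 fold change of KO over WT for each tested gene at 8 weeks (horizontal) and 16 weeks (vertical). Colours mark genes past the test at 16 weeks, at 8 weeks or at both; the 25 genes past it at both times lie on the same side of 0 at both, and genes with no count in a group, such as A1cf, are drawn at a fitted value that depends on the model.

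Between WT-16 and WT-8, 7285 of 15503 genes differed, 3484 higher and 3801 lower at 16 weeks. Time was not separable from sequencing: the 16-week samples had a pair of count files each and the 8-week samples a single file, and the 18S share separated the times. With that share as a covariate no gene passed in edgeR, and no gene is named for this comparison.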

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

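The tests of other groupings of the libraries, of the pooled spread and of the Esr1 and A1cf signals were chosen after the results were seen, and the test of the 18S share and those of Sft2d1 before.

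In 15 of 156 groups of values a library lay far from the others, where chance alone gives about 7.8 (1 in 20 groups). Replicate 3 of WT-16 had a total of 19.7 M counts (the next 10, the lowest 8.63), a TMM factor of 1.1 (others 0.455 to 0.613) and 1.89 CPM of Nmrk2. Replicate 5 of WT-16 stood out for Acta1 (50.6 CPM), Ptgds (120 CPM) and Pirt (4.83 CPM). In KO-16, replicate 1 stood out for Irs2 (13.1 CPM) and Tcp11l2 (31 CPM), and replicate 4 for Otud1 (26 CPM). At 8 weeks replicate 1 of WT-8 stood out for Esr1 (1310 CPM) and A1cf (2.25 CPM), replicate 5 of WT-8 for Acot1 (10.4 CPM), and replicate 3 of KO-8 for Esr1 (1660 CPM), Cilp (49.5 CPM) and Bcl2l11 (6.15 CPM).

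For 14 gene lists the effect of the knockout differed between 16 and 8 weeks in the camera test of the difference. The median difference was 1.25 for the matrix list, 1.06 for hypertrophy, 2.6 for erythroid genes, 0.54 for ATF4 targets, 0.43 for glycolysis and 0.3 for endothelial markers. It was -0.56 for fatty acid oxidation, -0.67 for PPAR-alpha targets, -0.29 for branched-chain breakdown, -0.2 for the tricarboxylic acid cycle, -0.22 for calcium handling, -0.6 for the circadian clock, -0.61 for mitochondrially encoded and -0.12 for nuclear-encoded respiratory chain genes. With an estimated correlation no list passed, the lowest adjusted p being 0.347 (PPAR-alpha targets), nor did any with fry (lowest adjusted p = 0.0744). Time was confounded with sequencing.

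Of 100 groupings of the 16-week libraries, the real one included, 1 called as many genes as the real one (3181, highest other 2541, with replicates 1 of WT-16 and KO-16 exchanged). This is the smallest share that 100 groupings can give. It makes chance alone unlikely for the count and decides on no single gene. The same held at 8 weeks (1 of 100; 31 genes, highest other 8), for the 8-week libraries alone (1 of 100; 1245, highest other 132) and for WT over time (1 of 100; 7285, highest other 3). For the interaction the real count was 0 with edgeR (2000 genes at an unadjusted p under 0.05; DESeq2 30, limma-voom 0), so that all 100 of 100 groupings reach it is fixed in advance and says nothing about chance. The highest of these interaction groupings called 2885 genes, with replicate 3 of WT-16 beside replicates 1 to 4 of KO-16. Its 16-week side lies close to the split by 18S share. It is also the genotype split with replicate 3 of WT-16 and replicate 5 of KO-16 exchanged, so the 2885 genes cannot tell these apart.

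The 3181 genes at 16 weeks were weighed against residual 18S rRNA, which the 8-week libraries lack. Of these genes 85.9% had the same sign at 8 weeks, and 66.5% of all genes tested did. The other 125 of 126 groupings of the 8-week libraries gave at most 84.0% and a median of 53.7%. The exact p = 0.00794 is the smallest that 126 groupings can give. The grouping at 84.0% was the real one with replicates 1 of WT-8 and KO-8 exchanged. The higher share in the real grouping argues against 18S rRNA as the sole cause of the set, and the remaining genes stay open. The 16-week libraries alone did not call 2825 of the genes, whether tested there or not. Of these 84.6% had the same sign, against at most 82.7% with the same exchange (exact p = 0.00794). They are most of the 3181, so this largely repeats the first comparison. It argues against the pooled spread as the sole source of those calls. A response to the loss of Mpc1 stays a hypothesis.

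High Esr1 counts and A1cf counts went together in 19 of 19 libraries: both were there in all 9 KO libraries and in replicate 1 of WT-8, and neither in the other WT libraries. That library had 82.4 CPM of Mpc1, against 63.7 to 77.0 CPM in the other WT-8 libraries, which argues against a KO-8 library under a WT label. A mixture scaled to its Esr1 would be 100% KO-8, with 10.8 CPM of Mpc1, so partial mixtures were not modelled. Induction of Esr1 by the loss of Mpc1 is argued against by the 1314 CPM of Esr1 in replicate 1 of WT-8. Reads of an inducible transgene assigned to these genes could give the joint presence. The labels name no transgene, however, and gene counts cannot show it. If the signal marks a transgene, KO and WT libraries differed in it as well as in Mpc1, save for replicate 1 of WT-8. The KO against WT comparisons at both times then could not separate the loss of Mpc1 from the transgene or its induction. Replicate 1 of WT-8 is a single library and cannot decide this, and no WT library of the later time carried the signal.

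Sft2d1, next to Mpc1, rose at both times. Strain variants around the targeted locus would change neighbours more often. In the fit to the 8-week libraries alone 1 of 16 genes within 2 Mb was called (6.2%, exact interval 0.158% to 30.2%) against 8.2% of the others (one-sided Fisher's exact p = 0.746), too few to decide. The gain of Sft2d1 per kb was at most 10.2% of the WT level of Mpc1, so reads running on from that locus stay open, since gene counts show no junctions. Its fold change grew by 0.19 from 8 to 16 weeks (95% interval -0.35 to 0.73), against a median of 0.35 for the 14 other genes, so a response growing with those genes could not be told apart from a constant rise.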

How the results depend on the processing

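The 18S covariate, the 18S sets, the fits without rRNA genes or male libraries and voom with quality weights were chosen after the results were seen. Of 3871 values of named genes called at 16 weeks, 3420 kept direction and side of the threshold and 450 kept direction alone; at 8 weeks 435 of 532 and 97 did. Under the alternatives the 16-week count (3181) was 356 with the 16-week libraries alone, 1649 with the 18S covariate, 1632 over and 81 under 20% 18S and 1706 without males, and 1462 to 4888 with a library left out. The 8-week count (31) was 79 with no filter, 120 with DESeq2, 72 with voom, 1245 with the 8-week libraries alone, 80 and 56 with the earlier and later 16-week file, 74 with the 18S covariate, 350 over 20% 18S and 1227 with voom and quality weights, and 15 to 29 with a library left out. The interaction count (0) was 43, 30, 80, 12 and 527 with no filter, DESeq2, over and under 20% 18S and quality weights, and 0 to 613 with a library left out. The WT time count (7285) was 0 with the 18S covariate, which separates the times, and 3379 under 20% 18S, and 6618 to 7122 with a library left out. The overlap (25) was 60, 86, 51, 207, 47 and 42 with no filter, DESeq2, voom, each time alone and the earlier and later file, and 49, 193, 10 and 575 with the 18S covariate, over and under 20% 18S and quality weights, and 13 to 27 with a library left out. Reversed at 16 weeks were Myl7, 2.64 over 20% 18S, and mt-Nd1, 0.0722 under 20% 18S (1 WT library). Sets of libraries have fewer samples; for the other shifts the cause was not tested. The smallest library, 8.63 M counts, limited low-count genes.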

Other observations

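The positions of the WT-8 libraries were computed after the Esr1 signal was seen. The genes used were those called in a fit to the 8-week libraries alone without the library in question, leaving out Mpc1, Mpc1-ps, Esr1 and A1cf. Replicate 1 of WT-8 lay nearer to WT in 806 of 935 such genes (86.2%), and its median position was 4.4% of the way to KO. In replicates 2 to 5 the shares nearer to WT were 87.8%, 85.8%, 90.6% and 80.3%.

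Replicates 1 and 5 of KO-16 had 46.7 and 152 CPM of Postn, against 376 to 422 CPM in the other KO-16 libraries, and 2563 and 2027 CPM of Lpl, against 1040 to 1400 CPM.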
